A study of Mus musculus with 2 samples.

How the data were processed

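Liver RNA from mouse embryos at embryonic day 14.5 was hybridized to 2 single-colour Affymetrix arrays, 1 from a wild-type liver sample and 1 from a liver sample of the genotype Prox1 f/f;Foxa3Cre, in which a Cre recombinase expressed under Foxa3 recombines a floxed Prox1 gene. The strain label is NMRI/C57Bl6 for both. Per the labels' protocols, total RNA was isolated with Trizol, and biotin-labelled cRNA was made from it by the Affymetrix one-cycle assay. The labels do not say how many embryos went into each RNA sample, which part of Prox1 is removed, or whether the arrays were hybridized together.

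The intensity values deposited by the authors are MAS5 signals, per the submitters' processing notes, with 1 value per probe set and array on a linear scale. MAS5 summarizes the perfect-match and mismatch probes of a probe set into 1 signal and scales each array to a target. The 2% trimmed mean was 500.0 on both arrays, which is how the common scaling was recognised, and the values were therefore used as deposited. The MAS5 version is not given in the sources used here, and detection calls were not used here. Because MAS5 subtracts mismatch signal probe by probe, dim probe sets scatter widely. Probe sets near the top of the scale can be compressed, and 227 probe sets exceeded a signal of 20000 on at least 1 array.

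Each array held 45101 probe sets, of which 64 were control probe sets and were left out. Gene names came from the platform annotation at GEO, with gene identifiers looked up in a RefSeq gene table of the assembly GRCm38.p6. The annotation gave 1 gene symbol for 34958 probe sets and several symbols for 932. A further 9160 were not listed and stay unnamed here. Of the probe sets with 1 symbol, 34754 had their gene identifier in the RefSeq table, which changed 0 symbols. Probe sets with several symbols or none name no gene, so a gene covered only by such probe sets was not analysed here, nor was Spp1, whose symbol no probe set carries in the annotation used. All columns of the value table belonged to a sample.

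A common floor of 112.6 signal units was set, the higher of the arrays' 50th percentiles, and lower values were raised to it before taking log2. A gene was represented by its probe set with the highest mean log2 signal and counted as measured on an array where that probe set was above the floor. The log2 difference is knockout minus wild type. A gene on the floor on 1 array has only a bound, written "at least N-fold", and where that bound is under 2-fold the gene is counted as between, although its true difference can be larger. The number of arrays limits the precision: with 1 array per genotype there are no replicates, no SD or standard error between samples, and no test between genotypes. No p-value for a genotype difference is given, and genes were counted by size, at 2-fold.

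A total of 25 gene lists was fixed before the data were examined, as were the size rule, the floor and the rule for named genes. The lists were hepatocyte secreted proteins, hepatocyte metabolic enzymes, hepatocyte transcription factors, cholangiocyte genes, the Notch pathway, the TGF-beta, activin and BMP pathway, basement membrane and laminin genes, hepatoblast genes, bile acid synthesis and transport, cholesterol and fatty acid synthesis, and complement, acute phase and iron genes. They also held erythroid, megakaryocyte, macrophage, granulocyte, lymphoid, endothelial, stellate and mesenchymal, mesothelial, pancreas, gut and stomach, muscle and heart, cell cycle, immediate early and stress, housekeeping and sex-linked genes. For each list the median log2 difference over its measured members was set against 10000 random gene lists of the same size, matched on mean log2 signal in 20 bins. The resulting percentile describes these 2 arrays and is not a test between genotypes. Named genes were Prox1, the 10 highest and 10 lowest log2 differences among genes measured on both arrays, the 5 largest bounds each way, and up to 4 members of each list with the largest absolute difference. The highest and lowest genes and bounds were taken among genes whose measured probe sets all differed in the same direction; list members were not held to this. A set of hepatic, biliary and signalling genes was also named whatever its values, and genes named outside the rule are marked as chosen after their values were seen.

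Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The counting and the random-list step were tested on simulated arrays with a robust SD taken from the real log2 differences, on 11189 genes. Among 50 genes simulated at each size, 58.0% of those changed 2-fold, 94.0% of those changed 4-fold and 96.0% of those changed 8-fold passed the 2-fold mark in the right direction. Of 10959 unchanged genes, 6 passed it, and real dim probe sets scatter more than these simulated ones. A list of 30 genes shifted by 0.5 was recovered at a median of 0.44, and 3 of 100 unshifted lists fell outside the 2.5th to 97.5th percentiles.

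Alternatives were median centring, quantile normalization, a lowess correction on signal, floors at the 30th and 60th percentiles, no floor, the median over a gene's probe sets, leaving out _s_at and _x_at probe sets, which can bind transcripts of several genes, and a 3-fold mark. Leaving out genes of the sex chromosomes, very bright list members or members shared between lists was added after seeing the data. No replicate could be left out.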

Results

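Gene expression was profiled in whole liver at E14.5 from 1 wild-type sample and 1 Prox1 conditional knockout sample. Prox1 encodes a homeodomain transcription factor of liver progenitors, and Foxa3 is a gene of the gut and liver endoderm, from which hepatoblasts arise. The comparison asks how the genes expressed in fetal liver, hepatocyte and bile duct genes among them, differ when Prox1 is deleted. Fetal liver at this stage is also a blood-forming organ, so the RNA comes from erythroid and other blood cells, endothelium and mesenchyme as well as from hepatoblasts. There were no replicates of either genotype, so every value below is a single measurement and every difference is between these 2 samples.

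The arrays had the same 2% trimmed mean, but dim genes tended to read higher on the knockout array. The median signal was 101.1 on the wild-type array and 112.6 on the knockout array, and 21588 and 22518 of 45101 probe sets lay above the floor. Of 18193 genes with a probe set of their own, 11397 were measured on at least 1 array, 812 of them on the knockout array only and 364 on the wild-type array only. The remaining 10221 were measured on both. Across the latter the log2 signals correlated with r = 0.96, a value across genes, which are not independent replicates. Their median log2 difference was 0.01, and the middle 95% of differences ran from -0.84 to 1.01. The robust SD of the log2 difference narrowed with signal. It was 0.46 for genes below a mean signal of 250, 0.34 between 250 and 1000 and 0.23 between 1000 and 5000. The tails did not narrow from the dimmest genes to the next brighter ones. The middle 95% ran from -0.79 to 1.10 below 250 and from -1.01 to 1.12 between 250 and 1000. The median log2 difference was 0.12 below 250 and -0.03 between 1000 and 5000, so bounds and counts of dim genes lean towards higher in the knockout. The ratio of 3′ to 5′ signal of the control probe sets, a sign of RNA integrity, was 0.77 and 0.76 for Gapdh and 1.25 and 1.32 for Actb in wild type and knockout. It was higher and differed more between the arrays for Tfrc (2.17 and 2.58) and Pcx (3.17 and 2.19).

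Prox1 itself was lower on the knockout array. Its brightest probe set read 340.3 in wild type and 221.8 in the knockout, a log2 difference of -0.62. The other probe sets were also lower, from 205.9 and 175.4 in wild type to 111.8 and 66.7, both below the floor, in the knockout, so they give only bounds of -0.87 and -0.64. Whether these probe sets lie in the part removed by Cre is not given in the sources used here, so the reading does not measure how complete the deletion was. Sex-linked genes also separated the arrays. Xist, the RNA that coats the inactive X chromosome, read 11467 in wild type and 365.7 in the knockout, while the Y-linked gene Eif2s3y read 0.87 and 1972. Uty and Kdm5d, also on the Y chromosome, were at least 2.80-fold and 2.68-fold higher in the knockout. This difference in sex-linked genes lies beside every gene group below.

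In all, 373 genes were at least 2-fold higher and 243 at least 2-fold lower in the knockout, together 5.4% of measured genes. Of these, 106 and 54 were on the floor on the other array. The counts rest on the floor, the filter and the size rule: they were 789 and 414 with the floor at the 30th percentile, 2265 and 1398 with no floor and no filter, and 99 and 102 at 3-fold. Where a gene had more than 1 measured probe set, all differed in the same direction in 147 of 157 higher genes and 58 of 63 lower genes. Among genes measured on both arrays, the lowest in the knockout was Car3, a cytosolic carbonic anhydrase, which went from 9304 to 249.7 and was 37.3-fold lower; the log2 difference of Car3 was -5.22 on this probe set, -3.97 on the other probe set measured on both arrays and -2.29 as the median over its 4 probe sets, of which 2 give only bounds. The genes that followed, apart from Xist, were Ahsg (fetuin-A, 13.2-fold lower), Pzp (an alpha-2-macroglobulin relative, 9.98-fold), F13b (coagulation factor XIII B chain, 9.01-fold), Aldh8a1 (an aldehyde dehydrogenase, 8.25-fold), Gldc (glycine cleavage, 7.41-fold), Mbl1 (mannose-binding lectin, 7.23-fold), C1s1 (7.08-fold) and C8b (6.78-fold), both complement components. Dropping below the floor in the knockout, Ccnb1ip1 was at least 22.0-fold lower, the cytochrome P450 Cyp3a11 at least 9.49-fold, the copper carrier ceruloplasmin (Cp) at least 8.75-fold, paraoxonase Pon1 at least 8.44-fold and the glucokinase regulator Gckr at least 8.41-fold. The other measured Cp probe sets had log2 bounds from -2.19 to -1.0024.

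At the upper end, Rpgrip1 was 13.8-fold higher in the knockout, Rnd2 7.21-fold, the receptor tyrosine kinase ligand Gas6 6.77-fold, the membrane serine protease Tmprss2 6.53-fold, Ermp1 6.24-fold, lactate dehydrogenase B (Ldhb) 6.09-fold, alcohol dehydrogenase Adh1 5.93-fold, the laminin beta chain Lamb1 5.76-fold, Npl 5.48-fold and the kinase Nrk 5.43-fold. The largest bounds belonged to Cubn, an endocytic receptor of absorptive epithelia, at 60.3 in wild type and 3765 in the knockout and so at least 33.4-fold higher. Apart from Eif2s3y they were followed by the ribonuclease Ang (at least 16.5-fold), Smim38 (at least 15.3-fold) and Clic6 (at least 14.45-fold). Some of these sizes rest on the brightest probe set. Rpgrip1 had 1 measured probe set of 4, the others being below the floor on both arrays. The other Ldhb probe sets had larger log2 differences, of 2.91, 3.38 and 3.87. Another Lamb1 probe set measured on both arrays had a log2 difference of 1.30, and other probe sets had bounds of 1.55 and 2.68 for Ang, 2.43 for Smim38, 2.81 for Clic6 and 4.47 for Cubn, and a value of 0.33 for Ermp1.

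**Figure D1:**
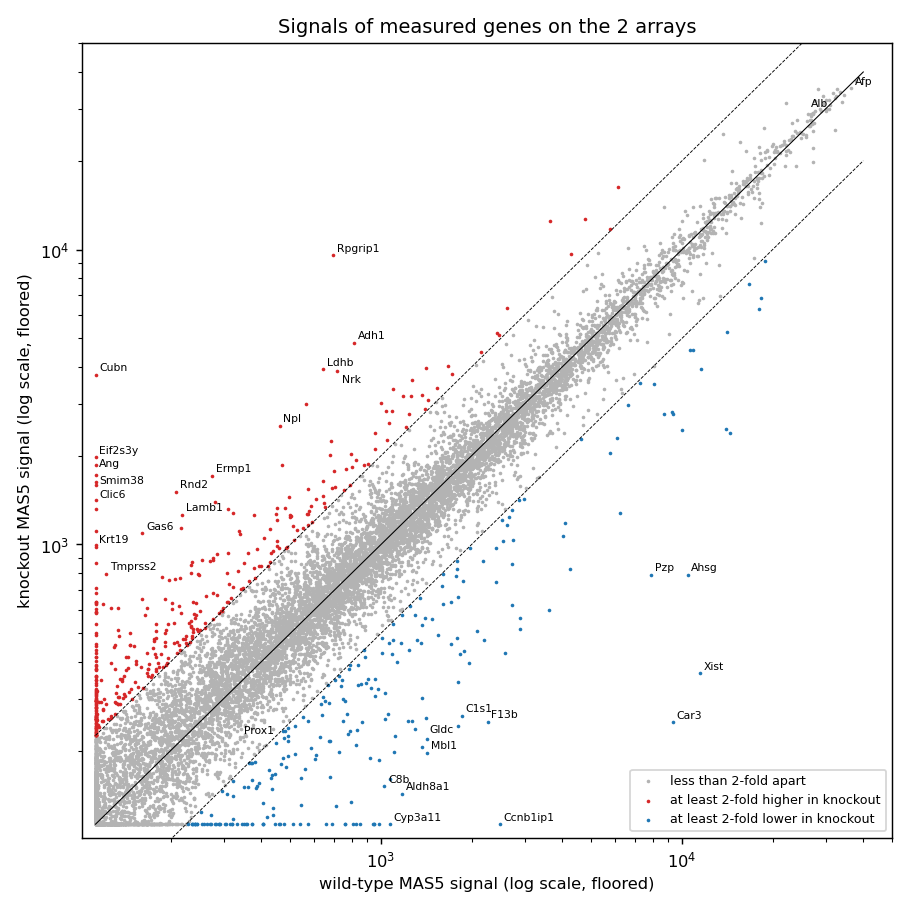
MAS5 signal of each measured gene in the knockout (vertical axis) against wild type (horizontal axis), both log scales with values below the floor of 112.6 raised to it; the solid line marks equal signal and the dashed lines 2-fold, grey points on either floor are bounds under 2-fold, with 1 array per genotype and no error bars. The 373 genes higher in the knockout (red) include a column on the wild-type floor headed by Cubn, and the 243 lower genes (blue) include Car3, Ahsg and Pzp far below the line, while Alb and Afp sit on it at the top of the scale.

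Plasma proteins made by hepatocytes were lower in the knockout as a group. Of 34 measured hepatocyte secreted proteins, 14 were at least 2-fold lower, 2 at least 2-fold higher and 18 between, and 31 were below 0. The median log2 difference was -0.81, and none of the 10000 random lists, whose middle 95% ran from -0.07 to 0.06, had a median as low. Besides Ahsg, Apoh (beta-2-glycoprotein I) went from 14470 to 2383, 6.07-fold lower. The higher members were the apolipoproteins Apoa4 (at least 12.6-fold, with a log2 bound of 2.54 on its other probe set) and Apoc3 (at least 4.38-fold). Albumin (Alb, 32396 and 33186) and alpha-fetoprotein (Afp, 36369 and 35212), the major secreted proteins of fetal liver, differed by 0.03 (just below 0 under quantile normalization and lowess correction) and -0.05 on the log2 scale, at signals near the top of the scale, where 83 genes above 20000 held 0 that were 2-fold apart. A dim Afp probe set went the other way, from 108.8 to 289.3, with a log2 bound of 1.36. The 23 measured complement, acute phase and iron genes had 10 at least 2-fold lower, 1 at least 2-fold higher and a median of -0.73, again below all random lists. With Cp, Mbl1 and C1s1, Saa4 led this list at 5.45-fold lower, and the higher member, named after its value was seen, was Saa3 (a log2 difference of 1.65).

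Hepatocyte metabolic enzymes were lower to a similar extent. Of 30 measured, 13 were at least 2-fold lower, 2 at least 2-fold higher and 15 between, with a median of -0.97, which no random list reached. Cps1, the entry enzyme of the urea cycle, went from 2580 to 427.6 and was 6.03-fold lower, and the cytochrome P450 Cyp2d10 was 6.71-fold lower. Adh1 and, named after its value was seen, Cyp2c70 (a log2 difference of 1.23) were the higher members. Cholesterol and fatty acid synthesis was lower by a smaller amount, with a median of -0.33 over 22 genes, also below all random lists, although 0 members were 2-fold lower and 1 was 2-fold higher. The sterol enzymes Hmgcs1 (1.92-fold lower), Dhcr7 (1.90-fold) and Lss (1.80-fold) stood against malic enzyme Me1, 3.30-fold higher. Bile acid genes lay in both directions. Among 17 measured, 2 were 2-fold lower (Slc27a5, 2.49-fold, and the bile salt export pump Abcb11, 2.04-fold) and 2 were 2-fold higher (the bile acid receptor Nr1h4, 3.66-fold, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at least 3.56-fold, with a log2 bound of 1.05 on its other probe set). The bile acid median of -0.26 lay at percentile 0.21 of the random lists.

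Hepatocyte transcription factors lay in both directions. Of 22 measured, 1 was 2-fold lower, 1 was 2-fold higher and 20 lay between, with 12 above 0 and 10 below 0. The median of 0.16 lay at percentile 91.3, within the range of random lists. The list as fixed also holds Lsr (a log2 difference of 0.70), which encodes a lipoprotein receptor and not a transcription factor. The direction of this median depends on the setting: it was -0.014 when a gene was taken as the median of its probe sets and -0.13 at percentile 2.27 without members that stand in another list, but 0.23 at percentile 99.4 with the floor at the 60th percentile. Cebpa, a driver of hepatocyte maturation, was 2.03-fold lower, from 1174 to 578.2. Hnf4a, a central hepatocyte regulator, was 1.46-fold lower, from 2280 to 1562. All 4 of its probe sets were below 0, with log2 differences from -0.85 to -0.04, the latter being nearly equal on the arrays. Nr1h4 was the higher member, and Foxa2 and Cebpb were 1.77-fold and 1.76-fold higher. The 19 measured hepatoblast genes had a median of 0.17, at percentile 98.1 (86.7 to 99.3 over the alternatives, and above the random range in 5 of 10), with 2 genes 2-fold higher and 0 lower. These were Hmga2, 2.44-fold higher, and Epcam, at least 2.42-fold, followed by Id3 at 1.90-fold and Lgr5 at 1.57-fold.

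A few genes of the cholangiocyte list were much higher in the knockout. Of 48 listed genes, 42 had a probe set of their own and only 25 were measured. Of 25 measured cholangiocyte genes, 5 were at least 2-fold higher, 0 were at least 2-fold lower, and 20 had a difference or a bound under 2-fold. The median was 0.25, at percentile 99.7 of the random lists, with 18 members above 0 and 7 below 0. The lowest, named after its value was seen, was Anxa4 (a log2 difference of -0.87). The higher genes were the keratin Krt19 (70.5 in wild type and 982.4 in the knockout, at least 8.72-fold), the tight junction claudins Cldn7 (at least 6.34-fold) and Cldn6 (at least 5.67-fold), the transcription factor Sox4 (2.69-fold) and the epithelial adhesion protein Epcam. All of these except Sox4 were below the floor in wild type. Another Epcam probe set, below the floor on both arrays, read 89.0 in wild type and 59.5 in the knockout. Sox9, an early biliary factor, read 48.5 and 127.4, only just above the floor in the knockout, so its bound was 1.13-fold; with the floor at the 30th percentile its log2 difference was 1.39. Its other probe sets were below the floor on both arrays and differed in direction. They read 6.52 and 88.2, and 58.5 and 22.1, in wild type and knockout. Krt7 read 80.1 and 113.5, the latter at the floor, and Onecut1 was below the floor on both arrays at 77.7 and 66.6. Onecut2 was 1.35-fold higher, with its 3 probe sets in the same direction, and E-cadherin (Cdh1) was 1.16-fold higher.

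Lists of Notch, TGF-beta and basement membrane genes had medians above 0, beyond the random range for 2 of 3 lists. Mesenchyme and vessels also express many of these genes, and the stellate and mesenchymal median was 0.94 and the endothelial median 0.36. Of 18 measured Notch pathway genes, 2 were 2-fold higher, Dtx4 (2.10-fold, with a second probe set in the other direction) and Notch1 (2.01-fold, with a second probe set at 189.9 and 191.6). As the median over probe sets both were less than 2-fold higher, and Notch1 was also under 2-fold in each rescaling. The Notch median was 0.19, at percentile 91.5 and within the random range (89.2 to 99.6 over the alternatives). Hes1 was 1.56-fold higher, Jag1 1.32-fold and Notch2 1.22-fold higher, and Dll4 1.47-fold lower. The TGF-beta, activin and BMP pathway had a median of 0.33 over 32 genes, at percentile 99.98, with 27 members above 0. Ltbp3 (at least 2.98-fold, with a log2 bound of 0.13 on its other measured probe set) and Tgfbi (2.26-fold) were 2-fold higher, Fstl1 was 1.90-fold higher, and hepcidin (Hamp), a BMP target, was at least 2.12-fold lower. Tgfbr2 was 1.24-fold higher on its brightest probe set while its other measured probe set was lower, and Tgfb2 was just above the floor in the knockout at 122.7. The 23 measured basement membrane and laminin genes had a median of 0.36, at percentile 99.99, with 21 above 0 and 3 at least 2-fold higher. These were Lamb1, with Lama1 (at least 2.76-fold) and the laminin receptor chain Itga6 (2.27-fold), and Sparc was 1.88-fold higher.

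Genes of hepatic mesenchyme and of granulocytes had the highest medians of the cell type lists. Of 27 measured stellate and mesenchymal genes, 13 were at least 2-fold higher, 0 were 2-fold lower and 26 were above 0, with a median of 0.94 that no random list reached. Collagen chains Col1a1 (3.96-fold) and Col6a1 (3.83-fold), Cdh11 (3.25-fold) and the mesenchymal transcription factor Hand2 (3.24-fold) led the list. Of 19 measured granulocyte genes, all were above 0 and 7 at least 2-fold higher, with a median of 0.93 that also exceeded all random lists. They included Fcnb (3.49-fold), Chil3 (2.95-fold), S100a9 (2.65-fold, from 6118 to 16234) and Ms4a3 (2.53-fold).

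Macrophage, endothelial and megakaryocyte genes had medians above the random range but below those of stellate and granulocyte genes. The median was 0.37 for 22 macrophage genes, above all random lists and led by the scavenger receptor Marco at 2.72-fold higher, with Aif1, Fcer1g and Adgre1 between 1.71-fold and 1.96-fold. It was 0.36 for 26 endothelial genes, at percentile 99.7, with 0 genes 2-fold apart and Sox18 (1.61-fold), Pdpn (1.60-fold), Ramp2 (1.51-fold) and Plvap (0.57 on the log2 scale) the farthest. It was 0.34 for 16 megakaryocyte genes, at percentile 99.8, with Itgb3 at least 2.49-fold higher (log2 bound of 0.0048 on its other probe set, at the floor), Gp6 at least 1.999-fold, Gp1bb 1.63-fold and Vwf 0.56 higher on the log2 scale. For 6 measured lymphoid genes it was 0.46, at percentile 97.8 (86.1 to 99.4 over the alternatives), with Ptprc 1.88-fold higher, Blnk 1.53-fold, and Cd72 and Pax5 at least 1.46-fold and 1.30-fold. For 9 measured mesothelial genes it was 0.43, within the random range at percentile 96.5 (73.6 to 98.5 over the alternatives), with Tcf21 2.64-fold, Upk3b 1.61-fold, Aldh1a2 1.42-fold and Bnc1 at least 1.35-fold higher. Erythroid genes, from the most abundant cells of the organ, had a median of -0.08 over 31 genes, at percentile 2.5 (1.60 to 8.27 over the alternatives). The embryonic globin Hbb-bh1 was the 1 member 2-fold lower (2.06-fold), the transferrin receptor Tfrc was 1.49-fold and Gata1 1.23-fold lower, and Car1 was 1.83-fold higher.

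**Figure D2:**
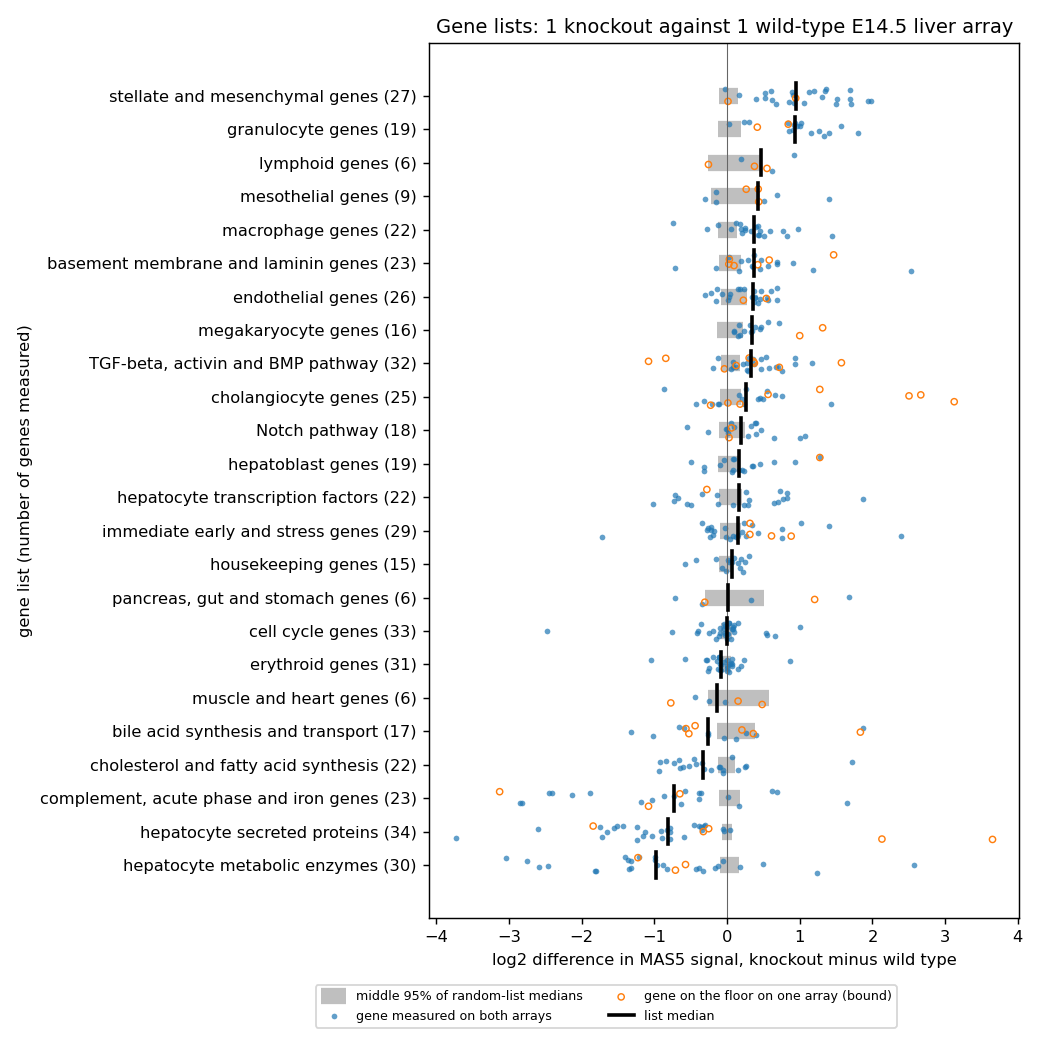
Log2 difference in MAS5 signal, knockout minus wild type, of each measured gene (points) in 24 gene lists, with the number measured beside each name; black bars are list medians, grey bars the middle 95% of medians of 10000 random lists matched on signal, and open orange points genes on the floor on 1 array, with 1 array per genotype. Hepatocyte enzymes, secreted proteins and complement genes lie to the left (medians -0.97, -0.81 and -0.73), stellate and granulocyte genes to the right (0.94 and 0.93), and erythroid and cell cycle genes near 0.

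Cell cycle, stress and housekeeping lists lay within the random range as reported. The 33 measured cell cycle genes had a median of -0.0042, at percentile 58.8, which ranged from -0.03 to 0.02 over the alternatives, although Cdk2 was 5.55-fold lower on its 1 measured probe set, and the cyclin-dependent kinase inhibitors Cdkn1b (1.68-fold lower), Cdkn1a (1.998-fold higher, with a log2 bound of 0.049 on its other probe set) and Cdkn1c (1.58-fold higher) differed in direction. Immediate early and stress genes had a median of 0.15, at percentile 93.3 (93.3 to 97.8 over the alternatives), with the heat shock gene Hspa1b 5.27-fold (log2 bounds of 1.08 and 1.66 on its other probe sets), Jun 2.65-fold (a log2 difference of 0.73 on its other probe set) and Ddit4 2.02-fold higher and Egr1 3.30-fold lower. Housekeeping genes had a median of 0.06, at percentile 91.9 (70.9 to 98.5 over the alternatives), with 0 of 15 at 2-fold, Tbp 1.34-fold lower, Rplp0 1.23-fold and Gusb 1.18-fold higher. Of the lists for neighbouring organs, only 6 pancreas, gut and stomach genes were measured, with a median of 0.01 at percentile 31.0, which ranged from -0.07 to 0.33 over the alternatives. The mucosal peptide Tff3 (3.18-fold) and villin (Vil1, at least 2.30-fold) were higher, and Fabp2 (1.64-fold) and Nkx2-3 (1.27-fold) lower. The 6 measured muscle and heart genes had a median of -0.14, at percentile 7.79, which ranged from -0.25 to 0.34 over the alternatives, with Actc1 at least 1.71-fold, Tnnt1 1.36-fold and Mylpf 1.19-fold lower and Acta1 at least 1.40-fold higher. The 4 measured sex-linked genes had a median of 1.45, at percentile 99.99, with Xist lower and the 3 Y-linked genes higher.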

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

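The tests of explanations in this part were chosen after the result was seen, as were the hepatic epithelial and embryonic globin lists, while the medians of the other lists were planned. Outside the comparison, 2680 probe sets that the annotation does not name were measured on at least 1 array. Of them, 52 were at least 2-fold higher and 33 at least 2-fold lower in the knockout, against 373 and 243 of 11397 measured genes. These are smaller shares than among the named genes, and without replicates they cannot be told apart from scatter.

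Hepatocyte secreted and metabolic genes were lower in the knockout array, with medians of -0.81 and -0.97. A smaller share of hepatic epithelial cells in the knockout sample would lower all genes of that epithelium alike. The 15 hepatic epithelial genes, all of them also in other lists, had a median of 0.23. Of these, 10 were above 0 (Krt8, Krt18 and Cdh1 among them) and 5 below 0 (Hnf4a at -0.55, Met at -0.50, Foxa3 at -0.35, Anpep at -0.31 and Gpc3 at -0.10). Their bootstrap 95% interval over genes was -0.10 to 0.29, above that of the secreted proteins (-1.16 to -0.38). These genes thus did not fall as far as the secreted proteins, but they were picked after their values were known. Some, such as Krt8, Krt18 and Cdh1, also stand in the cholangiocyte list. The comparison therefore cannot decide, and a smaller hepatic share stays open. A younger knockout embryo could give a less mature liver, and the 3 embryonic globin genes, which decline with age, had a median of -0.24 at percentile 3.06, which goes against a younger embryo but lies within the range of random lists, so it stays open. The sex of the embryos cannot be told apart from genotype, since Xist differed by -4.97 between the only 2 arrays. Loss of Prox1, the difference the design names, also stays open and untested, as there are no replicates.

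Stellate, mesenchymal and granulocyte genes were higher in the knockout array, with medians of 0.94 and 0.93. A smaller hepatic share would raise the markers of all other cell types alike. The stellate and mesenchymal median exceeded the endothelial median by 0.59 (bootstrap 95% interval over genes 0.39 to 1.09). The granulocyte median exceeded the endothelial median by 0.58 (0.47 to 0.90). On these arrays the lists thus did not rise alike. However, the stellate and granulocyte lists were singled out for their high medians, and the intervals are over genes, not samples. The comparison therefore cannot decide, and a smaller hepatic share stays open. So does a shift common to macrophage, endothelial and megakaryocyte genes (medians 0.37, 0.36 and 0.34). The stellate and mesenchymal excess over the erythroid median was 1.02 (0.76 to 1.41), but several erythroid genes read above 20000, where values can be compressed, and without them the median log2 difference of erythroid genes was -0.0856. Tissue attached at dissection could bring mesenchyme, and the mesothelial median of 0.43 lay at percentile 96.5 (73.6 to 98.5 over the alternatives) while muscle and heart genes lay at -0.14. The 6 measured pancreas, gut and stomach genes had a median of 0.01, with 2 at least 2-fold higher (Tff3 and Vil1) and 3 below 0. Cubn, Cldn2 and S100g, in none of these lists, were below the floor in wild type and above it in the knockout. Krt19, Cldn6, Cldn7 and Epcam of the cholangiocyte list read likewise. Whether any of these genes came from attached tissue was not tested. Attached tissue stays open, as the neighbouring-organ lists have few measured genes. Whether stellate cells or granulocytes changed with genotype is untested.

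Among genes at least 8-fold apart, Ccnb1ip1 (lower), Ang and Rpgrip1 (both higher) fall within 20 measured genes on chromosome 14 in the gene order of GRCm38.p6. There were 24 such genes among 11381. Random gene orders held a window as full in a share of 0.0163 (0.0489 after Benjamini-Hochberg adjustment over 3 fold thresholds). At 2-fold and 4-fold the shares were 0.149 and 0.738 (adjusted 0.224 and 0.738). The block was seen before it was tested, and only the 8-fold threshold gave a low share. Ang reaches 8-fold only on its brightest probe set, with log2 bounds of 2.68 and 1.55 on the others. Rpgrip1 had 1 measured probe set of 4. Chance placement therefore stays open. From Ccnb1ip1 to Supt16, 16 measured genes include 4 at least 2-fold higher (with Pnp at 2.26-fold and Rnase4 at 2.19-fold) and 2 lower (with Supt16 at 2.03-fold). This stretch was bounded by the 8-fold genes themselves plus the next gene, Supt16, so its counts are no separate evidence. Strain haplotypes that differ between the embryos may produce such a block, but this was not decided: 2 of the 8-fold genes were higher and 1 lower, directions known when the block was found and no evidence for a haplotype over other causes.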

How the results depend on the processing

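Prox1 stayed lower under all 8 alternatives, from -0.70 to -0.62, and no named gene at least 2-fold apart and no list outside the random range changed sign where it had a value. Some medians within the random range did: those of hepatocyte transcription factors (2 alternatives), pancreas, gut and stomach genes (2), muscle and heart genes (2) and cell cycle genes (4). So did the genes Alb, Krt7 and Tgfbr2, each under 2-fold apart. The counts of 373 higher and 243 lower genes depended on the floor and the filter: they were 789 and 414 with a floor at the 30th percentile, and 2265 and 1398 with no floor and no filter, where more dim probe sets enter; at a 3-fold mark they were 99 and 102. Under the scalings they ran from 335 to 363 and from 248 to 267, and without genes on chromosomes X and Y (added after seeing the data) they were 356 and 238. The median of the hepatocyte secreted proteins was -0.76 under quantile normalization, -0.895 with the floor at the 30th percentile and -0.8949 without one, -0.86 with the floor at the 60th percentile and -0.98 without members over a signal of 20000, each below all random lists. The hepatocyte transcription factor median was -0.014 as the median over measured probe sets and -0.13 without members that stand in another list, where it reached percentile 2.27, but 0.23 at percentile 99.4 with the floor at the 60th percentile; the cause was not tested. The cholangiocyte median was 0.34 without _s_at and _x_at probe sets, without members over 20000 and without shared members, and its lowest percentile was 97.6. The Notch pathway ranged over percentiles 89.2 to 99.6, hepatoblast genes over 86.7 to 99.3, lymphoid genes over 86.1 to 99.4, mesothelial genes over 73.6 to 98.5, stress genes over 93.3 to 97.8, housekeeping genes over 70.9 to 98.5 and erythroid genes over 1.60 to 8.27, so their place against random lists depends on these settings. Of 250 list medians under alternatives 211 moved by less than 1 SD of random-list medians, and of 1027 named gene values 913 moved by less than the robust SD of genes measured on both arrays. Sox9 is limited by the floor: on its brightest probe set the log2 difference was 0.18, and 1.39 with the floor at the 30th percentile. Its other probe sets, below the floor used here on both arrays, differed in direction, so the size of 1.39 rests on 1 probe set. No paired analysis was possible because each group holds 1 array, and for the same reason no replicate could be left out and no other split of the samples exists.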

Other observations

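Apart from Cubn and Apoa4, the genes named here were chosen after their values were seen. Of the endocytic receptor complex formed by cubilin, amnionless, megalin and the adaptor Dab2, Cubn was at least 33.4-fold higher, Amn 2.81-fold higher (113.6 to 319.0, on the verge of the floor in wild type) and Dab2 2.22-fold higher on 4 measured probe sets, while Lrp2, which encodes megalin, was below the floor on both arrays (94.0 and 89.3). The 3 measured members had a median log2 difference of 1.49, at percentile 99.98 of random lists. This set was picked after its values were seen, so the percentile is no evidence of enrichment. The claudin Cldn2 was at least 11.7-fold higher, the retinaldehyde dehydrogenase Aldh1a1 at least 14.1-fold, Apoa4 at least 12.6-fold and the calcium-binding protein S100g at least 8.86-fold. The fatty acid binding protein Fabp1, shared by liver and gut, was 2.68-fold lower, from 18352 to 6859. Miox and the anion transporter Slc22a8, both known from kidney, were at least 6.73-fold and 4.52-fold lower.

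The P1 cre control transcript, spiked into the hybridization cocktail, has the sequence of the recombinase used in the knockout, and its 4 probe sets were higher in the knockout by a median log2 ratio of 0.13. The 14 bioB, bioC and bioD probe sets of the same cocktail had a median of 0.09, ranging from -0.16 to 0.29, so the cre reading lay within their range. Outside Xist, 360 measured genes on chromosome X had a median log2 difference of 0.075, and 18 of them were at least 2-fold apart. Of the 40 nearest measured neighbours of Prox1 on chromosome 1, in the gene order of GRCm38.p6, 1 was at least 2-fold apart, Mark1, which was higher in the knockout with a log2 difference of 1.01.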
